A study of Homo sapiens with 6 samples.

How the data were processed

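RNA sequencing was done on ARPE-19, an established human retinal pigment epithelial line. Of the 6 libraries, 3 came from control cells, called NC, and 3 from cells overexpressing CD51-ICD, called OE CD51 ICD here. CD51 is the integrin alpha V subunit, the product of ITGAV, and the group names and replicate numbers come from the sample titles. Per the labels' protocols, total RNA was taken with TRNzol reagent or a Quick-RNA column kit, without saying which served which library, and messenger RNA libraries were made with a SMARTER kit. The submitters' processing notes name the hg38 build. The aligner, the counting program, their versions and the use of strand are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart.

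The authors deposited a table of whole-number gene counts and a table of FPKM values for the same 6 libraries, with 58735 genes each. Per the file headers, both give an Ensembl gene ID, symbol, GRCh38 coordinates, biotype and gene length in bases, and all IDs and coordinates matched the GENCODE 29 annotation. Of these genes, 26470 had at least 1 count in some library. The deposited FPKM values were the same counts divided by gene length and by 1 constant per library, which was 0.961 to 1.05 times the library's total count. No library was pooled in the deposited tables.

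The counts as deposited were tested with edgeR 4.0.16 in R 4.3.3. Low-count genes were removed with filterByExpr, which left 13787 genes, libraries were scaled by TMM, and glmQLFit and glmQLFTest compared OE CD51 ICD with NC, two-sided, with Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05, and a second count required a change of at least 2-fold. Levels are CPM, counts scaled to library size and TMM factor. The standard error of a log2 fold change was derived from the F statistic of the test. Total counts ran from 13616694 to 16934668 per library. A gene with no count in a group was set against a floor of 3 counts over that group, which covers counting error only. In simulated counts, drawn on 13787 genes with 200 changed, edgeR recovered 78% of the genes changed by a log2 fold of 1 and 97% of those changed by 2. Of its calls, 5.41% were false. The simulation held equal numbers of rises and falls and no GC or chromosome trend. These shares need not hold where many more genes change, as in these data.

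Before the data were examined, 39 gene lists, the test design, the rule for naming genes and a set of processing alternatives were fixed. The lists covered EMT transcription factors, mesenchymal and contractile genes, extracellular matrix, matrix proteases, epithelial junctions, RPE identity, TGF-beta, integrins, YAP/TAZ, Wnt, Notch, gamma-secretase, complement and macular degeneration genes, inflammatory cytokines, interferon response, antigen presentation, mitosis, DNA replication, p53 targets, senescence, oxidative stress, unfolded protein response, heat shock, immediate early genes, glycolysis and hypoxia, oxidative phosphorylation, mitochondrially encoded genes, cholesterol synthesis, lysosome and autophagy, ribosomal proteins, secreted growth factors, replication-dependent histones and 7 sets of cell type markers. Lists with at least 5 tested members, 34 in all, were tested with camera in limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. Members were counted as past the threshold over all genes tested and adjusted over the list alone.

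The naming rule took ITGAV, and the 6 largest rises and 6 largest falls among called protein-coding genes with a mean of at least 5 CPM and groups that did not overlap. From each primary list it took up to 3 called members in the leading direction and 1 in the other. It also took 2 members from each of the 8 qualifying secondary lists with the smallest camera p and from the histone list. This gave 53 different genes, of which 1 is not reported here, nor are some other list members. Other list members named in the text were chosen after their values were seen, as examples or because a count was small.

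Library measures (total count, genes detected, mitochondrial share, share of the 10 most abundant genes) were compared by a two-sided exact permutation test, which with 3 libraries against 3 cannot give a p below 0.1. Alternatives comprised RLE, upper-quartile and library-size scaling, DESeq2 1.42.0, limma-voom, other low-count filters, protein-coding genes only, limma on log2(FPKM + 1) and log2(FPKM + 0.1), leaving out each replicate in turn, and the replicate number as a block. Removal of each library's trend with GC content or gene length, as loess offsets, and leaving out chromosome 11 were added after seeing the data. GC content was taken from the longest GENCODE 29 transcript of each gene and was had for 99.96% of tested genes. Tables and plots were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.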

Results

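Gene expression was measured in ARPE-19 retinal pigment epithelial (RPE) cells, in 3 control libraries (NC) and 3 libraries of cells overexpressing CD51-ICD. The series title places the work on osteopontin (SPP1) and integrin alpha V (ITGAV) signalling between microglia and RPE, epithelial-mesenchymal transition (EMT) and dry macular degeneration. The question for the comparison is which genes differ when the CD51-derived fragment is overexpressed. Total counts were 16934668, 13616694 and 14728515 in NC replicates 1, 2 and 3, and 15640428, 14620860 and 14577912 in the corresponding OE CD51 ICD replicates. The labels do not say that libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. All values are means ± SD over n = 3 libraries per group unless stated.

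ITGAV (ENSG00000138448, chromosome 2, 186590065 to 186680901, GRCh38) was 98.4 ± 12.9 CPM in NC and 448 ± 83.5 CPM in OE CD51 ICD, a 4.54-fold rise (log2 2.18 ± 0.11 SE, adjusted p = 1.47e-16). A count over the whole gene does not separate the construct from the cell's own ITGAV transcript. SPP1, its ligand gene named in the title, had 6 counts over the NC libraries and 3 over the OE CD51 ICD libraries and was not tested.

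Overexpression went with a broad change in the transcriptome. More members were higher than lower in the matrix, TGF-beta, integrin, secreted growth factor and unfolded protein lists, and more were lower than higher in the DNA replication and mitosis lists. Each of these lists was past the threshold by camera, and none was with an estimated correlation (adjusted p = 0.110 to 0.244 with an estimated correlation). Of 13787 genes tested, 3469 were higher and 3559 lower in OE CD51 ICD at an adjusted p under 0.05 (edgeR's quasi-likelihood test), and 950 were higher and 804 lower by at least 2-fold. The groups did not overlap in 57.5% of genes, where chance gives 10%. The biological coefficient of variation was 9.44%.

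The 6 largest rises were in COL20A1, ANGPTL4, COL1A1, FOXS1, SERPINA9 and DHRS2. COL1A1, the alpha-1 chain of type I collagen (ENSG00000108821, chromosome 17), went from 32.9 ± 9.94 to 1452 ± 201 CPM, a 44.3-fold rise. ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose from 0.764 ± 0.394 to 39.3 ± 16.5 CPM, and the forkhead factor FOXS1 from 1.18 ± 0.468 to 51.2 ± 2.23 CPM. The serpin SERPINA9 rose 39.1-fold and the dehydrogenase DHRS2 36.8-fold. COL20A1, a collagen gene, had no count in any NC library and 495 counts in OE CD51 ICD, which is at least 174-fold higher against a floor of 3 counts over the NC group.

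The largest falls were led by FOXQ1, a forkhead factor, which went from 33.1 ± 4.79 to 0.642 ± 0.127 CPM (log2 -5.67 ± 0.21 SE, adjusted p = 1.69e-19). ID2, which encodes an inhibitor of basic helix-loop-helix factors, fell from 23.6 ± 1.84 to 2.42 ± 0.877 CPM. The cell cycle factor gene E2F2 fell from 26.2 ± 1.82 to 2.70 ± 0.612 CPM. SEMA4A, HSD17B2, which encodes an enzyme that oxidises estradiol and testosterone, and TMEM158 had log2 fold changes of -3.16, -3.06 and -2.91.

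**Figure D1:**
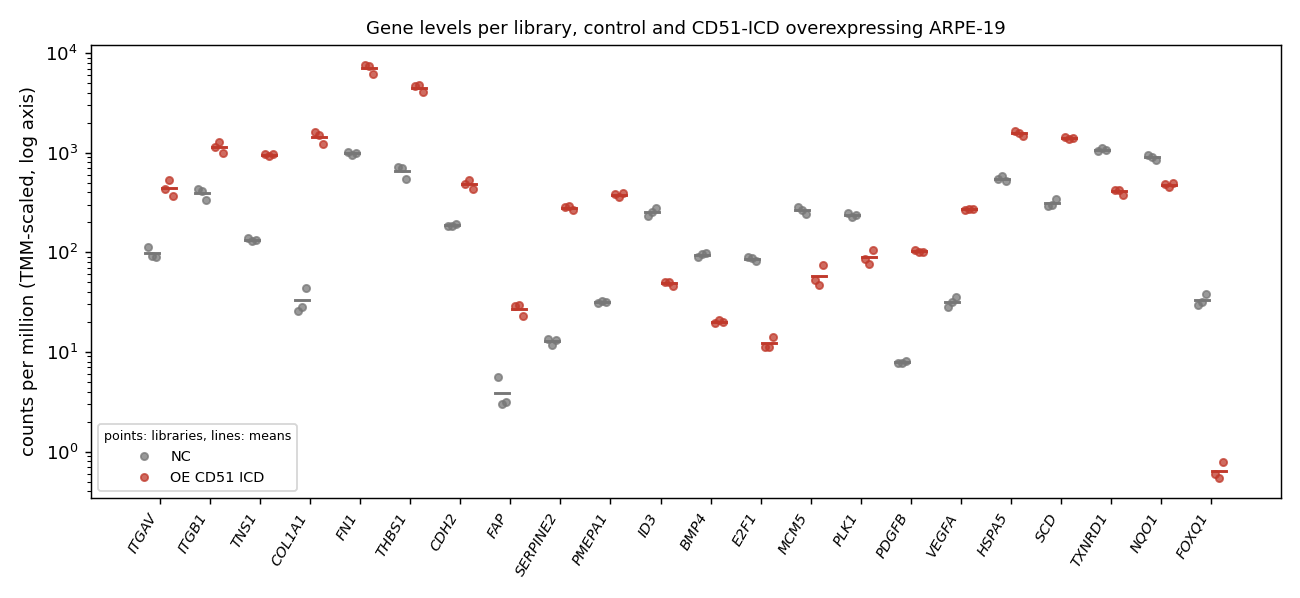
CPM per library (points, log axis) and group means (lines) for 22 of the named genes, with 3 NC and 3 OE CD51 ICD libraries each. The groups are apart for each gene shown: FN1 averaged 992 CPM in NC and 7043 CPM in OE CD51 ICD, and E2F1 86.0 and 12.2 CPM.

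Of 46 genes of the extracellular matrix list, 33 were tested, of which 20 were higher, 4 were lower and 9 did not pass. The counts adjusted over the list alone were 20 and 4. COL1A2, of the same list, had no count in NC and 12 counts over OE CD51 ICD and was not tested. FN1, fibronectin, rose from 992 ± 40.8 to 7043 ± 769 CPM and THBS1, thrombospondin 1, from 658 ± 94.1 to 4498 ± 417 CPM. The crosslinking enzyme gene LOX, COL4A1, SPARC and FBN1 had log2 fold changes of 2.09, 2.28, 1.85 and 1.48. The 4 lower genes were COL6A1 (15.2 ± 2.38 to 5.64 ± 0.149 CPM), COL12A1, FBN2 and FBLN2. The list was past the threshold by camera (adjusted p = 9.61e-09; adjusted p = 0.169 with an estimated correlation). Among 27 matrix protease and inhibitor genes, 11 were higher, with MMP2, PLAU and ADAM19 in the lead (log2 2.85, 2.95 and 3.15), and 8 were lower, among them TIMP2 and MMP15. The counts adjusted over the list alone were also 11 and 8, and the list was not past the threshold (adjusted p = 0.395).

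Mesenchymal and contractile genes were higher in 12 and lower in 2 of 20 tested members, with 12 and 2 adjusted over the list alone. CDH2, N-cadherin, rose from 186 ± 4.45 to 483 ± 47.7 CPM, CALD1, caldesmon, from 95.9 ± 14.2 to 330 ± 62.0 CPM, and FAP, a protease of activated stromal cells, from 3.88 ± 1.45 to 27.1 ± 3.44 CPM. TAGLN rose by 1.84 and VIM by 0.43 on the log2 scale. ACTA2, smooth muscle actin, was 33.3 ± 3.10 and 32.8 ± 2.93 CPM and did not pass the test. The lower genes were S100A6 and DES (1.70 ± 0.467 to 0.760 ± 0.237 CPM, adjusted p = 0.0121). The list was past the threshold (adjusted p = 8.94e-05; adjusted p = 0.110 with an estimated correlation). The DES call was lost under DESeq2, in limma on log2(FPKM + 1) without a filter, without NC replicate 1 and without OE CD51 ICD replicate 1 (adjusted p = 0.0630, 0.0719, 0.0913 and 0.0832; 0.0103 to 0.0913 over its alternatives). It was also lost with the GC trend removed, chosen after seeing the data (adjusted p = 0.0521).

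EMT transcription factors moved both ways. Of 11 tested, SNAI1, TCF4, SOX9 and ZEB1 were higher and FOXM1, TWIST1 and TCF3 lower. SNAI1, a repressor of E-cadherin, rose from 1.72 ± 0.296 to 10.2 ± 1.08 CPM, TCF4 from 1.53 ± 0.222 to 9.25 ± 0.815 CPM and SOX9 from 68.0 ± 9.63 to 106 ± 9.79 CPM. FOXM1, a driver of cell division genes, fell from 150 ± 9.63 to 69.6 ± 12.4 CPM, and its locus overlaps RHNO1 and ITFG2. Adjusted over the list alone, 6 were higher and 3 lower, and the list was not past the threshold (adjusted p = 0.507).

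Epithelial genes were also divided. Of 24 tested junction and keratin genes, 10 were higher and 5 lower, with the same numbers adjusted over the list alone, and the list was not past the threshold (adjusted p = 0.250). Among the higher genes were DSC2 and DSG2, which encode desmosomal cadherins, and CLDN4, a claudin. DSC2 rose from 7.39 ± 1.35 to 38.0 ± 7.23 CPM, DSG2 from 41.3 ± 4.05 to 90.6 ± 10.5 CPM and CLDN4 from 11.6 ± 2.34 to 38.6 ± 6.21 CPM. The 5 lower genes were PKP3 (5.53 ± 1.74 to 2.36 ± 0.688 CPM), CGN, CRB3, KRT19 and ELF3. The PKP3 call was lost in limma on log2(FPKM + 1) without a filter (adjusted p = 0.0649; 1.82e-06 to 0.0649 over its alternatives). KRT8 was 3717 ± 189 and 3461 ± 237 CPM and KRT18 1538 ± 68.8 and 1444 ± 143 CPM, and neither passed the test. CDH1, E-cadherin, had 5 counts over NC and 13 over OE CD51 ICD and was not tested.

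Of 44 RPE identity genes, 24 were tested, of which 9 were higher and 9 lower, also when adjusted over the list alone. By at least 2-fold, 2 were higher and 7 lower. PAX6, on chromosome 11 and overlapping ELP4, rose from 38.8 ± 2.005 to 58.5 ± 2.35 CPM. BMP4 fell from 94.8 ± 5.04 to 20.1 ± 0.531 CPM. The retinol dehydrogenase genes RDH10 and RDH5 and the pigment cell factor MITF fell by 1.88, 1.33 and 0.56 on the log2 scale, while OTX2 had a log2 fold change of 0.06 and did not pass. RLBP1 and PMEL, of the same list, were higher. RLBP1 went from 1.91 ± 0.350 to 3.32 ± 0.433 CPM and PMEL from 8.93 ± 1.99 to 15.6 ± 1.09 CPM. The list was not past the threshold (adjusted p = 0.574). Its median log2 fold change was 0.06, its mean -0.13 and its camera direction lower. The median was -0.00 with library size as the only scaling and -0.02 with the GC trend removed.

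TGF-beta pathway genes and early targets rose in 27 and fell in 9 of 40 tested members, with 27 and 9 adjusted over the list alone. SERPINE2, a protease inhibitor, rose from 12.8 ± 0.877 to 281 ± 13.7 CPM, PMEPA1, a feedback inhibitor of the pathway, from 31.5 ± 0.882 to 379 ± 15.4 CPM, and LTBP2 from 240 ± 14.8 to 1362 ± 25.8 CPM. TGFBI, SKIL and SMAD7 had log2 fold changes of 2.30, 1.90 and 0.99. The 9 lower members held the BMP targets ID1, ID2, ID3, ID4 and SMAD6, the ligand BMP2 and the decoy receptor BAMBI besides SMAD3 and FST. The BMP receptor genes BMPR2 and ACVR1 were higher, as was NOG, which encodes a BMP antagonist. ID3 fell from 254 ± 23.3 to 49.1 ± 2.40 CPM. The list was past the threshold (adjusted p = 6.97e-05; adjusted p = 0.1505 with an estimated correlation).

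Integrin and adhesion genes rose in 27 and fell in 6 of 37 tested members, with 27 and 6 adjusted over the list alone. TNS1, tensin 1, rose from 134 ± 4.04 to 951 ± 25.03 CPM and ITGB1, the beta-1 subunit, from 396 ± 52.3 to 1136 ± 137 CPM. The alpha V partners ITGB3 and ITGB5 rose by 1.88 and 1.01 on the log2 scale, and VCL and ITGA5 by 1.16 and 1.04. ITGA7, whose locus overlaps BLOC1S1, fell from 191 ± 14.9 to 106 ± 4.30 CPM, and the other lower genes included ITGB8 and VTN. The list holds ITGAV itself and was past the threshold (adjusted p = 1.13e-06; adjusted p = 0.165 with an estimated correlation).

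Secreted growth factor genes rose in 14 and fell in 3 of 25 tested members, with 14 and 3 adjusted over the list alone. PDGFB rose from 7.86 ± 0.168 to 103 ± 2.94 CPM and VEGFA from 31.8 ± 3.93 to 270 ± 4.41 CPM, with PDGFA up by 3.37 on the log2 scale. FGF5, PDGFD and BDNF fell. The list was past the threshold (adjusted p = 8.68e-05; adjusted p = 0.110 with an estimated correlation).

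Other signalling lists held members in both directions and none was past the threshold by camera. YAP/TAZ genes were 13 higher and 10 lower of 30 (adjusted p = 0.804), with CTGF up by 3.47 and AMOTL2 at -1.08 on the log2 scale. The median of that list was -0.08, or 0.06 with the GC trend removed, and its mean was 0.08. Wnt genes were 14 higher and 9 lower of 28 (adjusted p = 0.507), with WNT5B at 2.68 and DKK1 at -1.52. Notch genes were 6 higher and 4 lower of 19 (adjusted p = 0.574): the ligand gene JAG1 was at 2.14, and the lower genes were NOTCH1 (-1.58), HES4, HES6 and NRARP. Among 13 gamma-secretase and sheddase genes, 5 were higher, ADAM10, ADAM17, APP and APLP2 among them, and PSEN2, APH1A and APLP1 were lower (adjusted p = 0.574). Adjusted over the list alone, all counts of these 4 lists were the same.

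**Figure D2:**
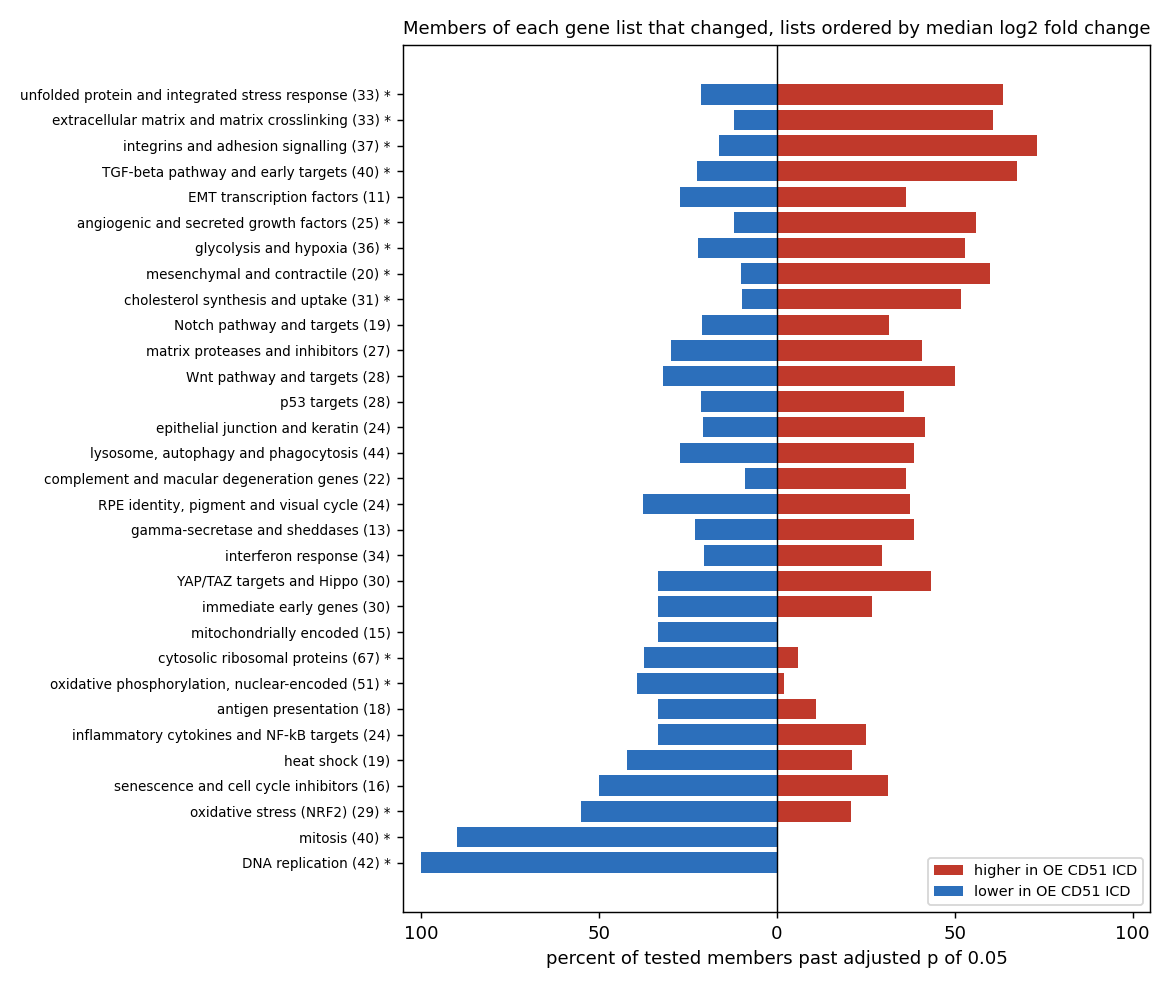
Percent of tested members (number in parentheses) of 31 gene lists that were higher (right) or lower (left) in OE CD51 ICD at an adjusted p under 0.05, ordered by median log2 fold change; a star marks a camera adjusted p under 0.05. The DNA replication list is lowest, with 42 of 42 members lower, and the unfolded protein list is highest, with a median of 0.79.

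DNA replication genes fell throughout the list, with 42 of 42 tested members lower, also when adjusted over the list alone. E2F1, a transcription factor of S phase genes, fell from 86.0 ± 3.65 to 12.2 ± 1.67 CPM and MCM5, a subunit of the replicative helicase, from 264 ± 19.2 to 57.9 ± 14.6 CPM. The median log2 fold change was -1.62 (adjusted p = 5.28e-27; adjusted p = 0.167 with an estimated correlation). Mitosis genes were lower in 36 and higher in 0 of 40, with the same counts adjusted over the list alone and a median of -0.86. PLK1 fell from 237 ± 12.8 to 89.1 ± 15.3 CPM, CDC20 from 242 ± 19.8 to 106 ± 18.0 CPM, and the log2 fold change of MKI67 was -1.11 (list adjusted p = 9.70e-14; adjusted p = 0.244 with an estimated correlation).

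Replication-dependent histone transcripts mostly lack a poly(A) tail, and 2 of 31 were tested: HIST1H1C fell from 6.15 ± 1.44 to 3.98 ± 0.679 CPM (adjusted p = 0.0147) and HIST1H4I did not pass. The HIST1H1C call was lost under DESeq2, in limma on log2(FPKM + 1) without a filter, without NC replicate 1 and without OE CD51 ICD replicate 2 (adjusted p = 0.0506, 0.0864, 0.146 and 0.0843; 0.00990 to 0.146 over its alternatives). It was also lost with the GC trend removed, chosen after seeing the data (adjusted p = 0.0832). Of 16 cell cycle inhibitor and senescence genes, 5 were higher and 8 lower, also over the list alone: CDKN2B, IGFBP3 and IGFBP5 rose by 3.22, 2.54 and 3.62 on the log2 scale with IGFBP7 and RBL2, and CDKN1A, CDKN1B and LMNB1 were among the lower. That list had a median of -0.32, a mean of 0.20 and a camera adjusted p of 0.714. Among 28 p53 targets, 10 were higher and 6 lower (10 and 9 adjusted over the list alone, list adjusted p = 0.507).

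Of 33 genes of the unfolded protein and integrated stress response list, 21 were higher, 7 were lower and 5 did not pass, and 22 and 8 when adjusted over the list alone. HSPA5, the chaperone BiP, rose from 551 ± 33.5 to 1571 ± 79.2 CPM and HYOU1, on chromosome 11, from 269 ± 8.02 to 713 ± 34.3 CPM. The 7 lower members were CEBPB, ATF5, TRIB3, PPP1R15A and the serine and glycine synthesis genes PHGDH, PSAT1 and SHMT2. The list was past the threshold (adjusted p = 3.42e-05; adjusted p = 0.110 with an estimated correlation). Heat shock genes were 4 higher (HSPB1, CRYAB, BAG3, DNAJB4) and 8 lower of 19, also over the list alone, and the list was not past the threshold (adjusted p = 0.293).

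Glycolysis and hypoxia genes were 19 higher and 8 lower of 36, and 20 and 8 adjusted over the list alone. Beside VEGFA and ANGPTL4, the prolyl hydroxylase genes P4HA1 and P4HA2 and LDHA had log2 fold changes of 1.71, 1.62 and 1.20, and STC2 and ADM fell (list adjusted p = 9.91e-04; adjusted p = 0.537 with an estimated correlation). Cholesterol and fatty acid synthesis genes were 16 higher and 3 lower, FASN and PMVK among them, of 31, and 17 and 3 over the list alone. SCD, stearoyl-CoA desaturase, rose from 311 ± 28.6 to 1403 ± 30.2 CPM, and FADS2, on chromosome 11 and overlapping FADS1 and FEN1, from 511 ± 20.1 to 917 ± 43.4 CPM (list adjusted p = 9.91e-04; adjusted p = 0.244 with an estimated correlation).

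Of 51 nuclear-encoded oxidative phosphorylation genes, 20 were lower, only UQCRC2 was higher and 30 did not pass, with the same calls adjusted over the list alone. ATP5MC1 was at 96.1 ± 3.95 and 57.0 ± 7.09 CPM and SDHA at 222 ± 9.74 and 150 ± 11.6 CPM. The median of the list was -0.18 (list adjusted p = 0.00212; adjusted p = 0.683 with an estimated correlation). Of 15 mitochondrially encoded genes, MT-ND1, MT-ND2, MT-ND3, MT-RNR1 and MT-RNR2 were lower (4 adjusted over the list alone, list adjusted p = 0.293). That list was past the threshold with the GC trend removed, a check chosen after seeing the data (adjusted p = 0.0139; 0.0139 to 0.952 over its alternatives); without that removal it had an adjusted p = 0.765 with an estimated correlation. NRF2 and oxidative stress genes were 6 higher and 16 lower of 29, also over the list alone. TXNRD1, thioredoxin reductase 1, whose locus overlaps the pseudogene RPL18AP3, fell from 1074 ± 35.7 to 410 ± 28.99 CPM and NQO1 from 899 ± 49.1 to 475 ± 24.0 CPM, while HMOX1 was higher (list adjusted p = 0.00212; adjusted p = 0.244 with an estimated correlation).

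Cytosolic ribosomal protein genes, many of which share reads with pseudogenes, were 4 higher (RPS13, RPLP2, RPL27A, RPS6) and 25 lower of 67, and 4 and 23 adjusted over the list alone, with a median of -0.15. RPS13, RPLP2 and RPL27A lie on chromosome 11. The list was past the threshold (adjusted p = 0.00436; adjusted p = 0.684 with an estimated correlation), but not with fry or without OE CD51 ICD replicate 2 (adjusted p = 0.0896 and 0.0633; 6.00e-05 to 0.252 over its alternatives apart from the estimated correlation). It was also lost with each library's gene-length trend removed, a check chosen after seeing the data (adjusted p = 0.252). Lysosome, autophagy and phagocytosis genes were 17 higher and 12 lower of 44, also over the list alone (list adjusted p = 0.507).

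Immune and inflammatory lists moved both ways, and none was past the threshold by camera. Complement and macular degeneration genes were 8 higher and 2 lower (VTN and C3) of 22, with CD59 and APOE at log2 fold changes of 1.26 and 1.86 (list adjusted p = 0.204). Cytokine and NF-kB genes were 6 higher and 8 lower of 24: IL11 rose from 2.99 to 53.9 CPM, and CXCL8 and SOD2 fell by 1.37 and 0.99 on the log2 scale (list adjusted p = 0.843). Interferon response genes were 10 higher and 7 lower of 34, with a median of -0.02 and a mean of 0.30 (list adjusted p = 0.584). Antigen presentation genes were 2 higher (ERAP1, ERAP2) and 6 lower of 18 (list adjusted p = 0.478), and immediate early genes 8 higher, led by JUNB at 3.15, and 10 lower, with JUN at -1.97 and FOSL1 at -2.12, of 30 (list adjusted p = 0.574). Adjusted over the list alone, the counts of these 5 lists were the same.

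Markers of other cell types were mostly near 0. Of 20 microglia and macrophage markers only CSF1R was tested, and it rose from 3.60 ± 0.894 to 32.9 ± 3.34 CPM; LAPTM5, next in level, was at 0.749 CPM in OE CD51 ICD. CSF1R lies directly downstream of PDGFRB on the same strand of chromosome 5. PDGFRB rose by a smaller factor, from 223 ± 13.2 to 389 ± 21.9 CPM. Whether reads running on from PDGFRB add to the CSF1R count was not tested. Of 6 tested fibroblast and pericyte markers, COL1A1, PDGFRB and PI16 were higher, COL1A1 being the most abundant in OE CD51 ICD, and the list was not past the threshold (adjusted p = 0.0557). It was past it with RLE factors, with fry, and without NC replicate 1, NC replicate 3 or OE CD51 ICD replicate 1 (adjusted p = 0.0388, 0.000201, 0.0305, 0.0463 and 0.0276; 0.000201 to 0.255 over its alternatives). It was also past it with the gene-length trend removed or without chromosome 11, both chosen after seeing the data (adjusted p = 0.0452 and 0.0467), and had an adjusted p = 0.248 with an estimated correlation. DCN had no count in any library, and COL3A1 and LUM were at 0.299 and 0.112 CPM in OE CD51 ICD. Of 6 tested glial markers CRYAB, VIM, RLBP1 and DKK3 were higher and GLUL lower, VIM being the most abundant (list adjusted p = 0.176).

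Of 7 tested photoreceptor markers OPN1SW was higher and GNGT2 and PDE6G lower, with ROM1 the most abundant at 18.7 ± 0.583 and 20.1 ± 3.002 CPM (list adjusted p = 0.507). Among endothelial markers ROBO4, on chromosome 11, was higher and EGFL7 and KDR lower of 3 tested, with ROBO4 the most abundant at 42.8 CPM in OE CD51 ICD. PMEL was higher and MITF lower of 2 melanocyte markers, with MITF at 26.6 ± 2.39 and 18.0 ± 4.27 CPM. PAX6, the most abundant, was higher and PAX8 lower of 4 embryonic kidney and neural stem markers.

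Of the 34 lists tested, 13 were past the threshold by camera, 8 higher and 5 lower. None of these calls held with an estimated correlation, where 7 lists had an unadjusted p under 0.05. The estimated correlations of the mesenchymal, unfolded protein and growth factor lists were -0.0004, -0.023 and -0.019, below the preset 0.01. Their unadjusted camera p still rose, from 2.10e-05, 5.03e-06 and 1.79e-05 to 0.00973, 0.00632 and 0.00879. A higher correlation between genes therefore does not account for the loss of these calls. The test with an estimated correlation thus differs from the preset one in more than the correlation. Its p-values, here and above, do not show by themselves that correlated genes undo a list's call. The median of each of the 13 kept its sign under RLE, upper-quartile and library-size scaling.

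Some measures of library make-up also differed between NC and OE CD51 ICD, and the design cannot separate such differences from the overexpression. The 10 most abundant genes took 9.36 ± 0.211% of counts in NC and 10.9 ± 0.128% in OE CD51 ICD (exact permutation p = 0.1, the smallest possible). Genes with at least 1 count numbered 19756 ± 365 and 20466 ± 206 (exact permutation p = 0.1). Mitochondrial genes took 4.30 ± 0.664% and 3.86 ± 0.240% (exact permutation p = 0.5), and total counts gave an exact permutation p of 0.8. Across genes, which are not independent replicates, log2 fold change fell with GC content (Spearman rho -0.32), from a median of 0.26 in the 10% of genes lowest in GC content to -0.30 in the 10% highest. Genes on chromosome 11 were 320 higher and 137 lower of 792, and their median with the GC trend removed was 0.26, against -0.10 to 0.05 for the 22 other chromosomes.

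**Figure D3:**
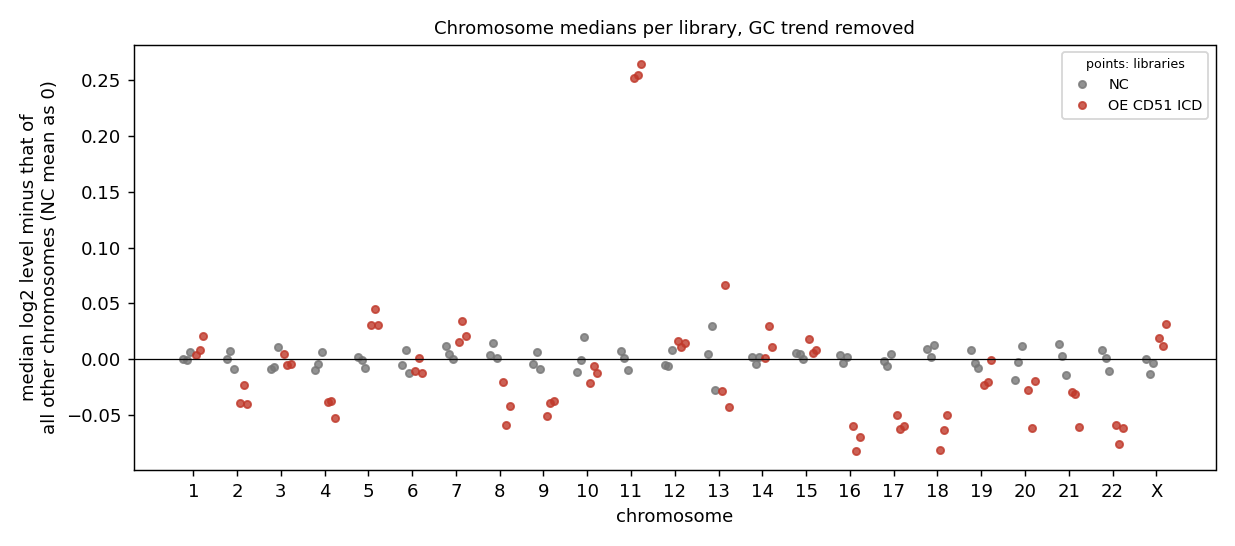
Median log2 level of the genes of each chromosome minus that of all other chromosomes, per library (points), with each gene's NC mean set to 0 and each library's GC trend removed. On chromosome 11 the OE CD51 ICD libraries lie at 0.25, 0.25 and 0.26, and the NC libraries between -0.01 and 0.01.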

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

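The trend removals and the fits without chromosome 11 were chosen after seeing the data. Under all 22 alternatives ITGAV stayed higher and past the threshold (log2 1.93 to 2.31), and counts of changed genes stayed within 1.5 times, at 2384 to 3801 higher and 2532 to 4051 lower. Leaving out each replicate in turn gave 3007 to 3641 higher and 2936 to 3654 lower. The direction with more calls turned with the scaling: 41.7% of calls were higher with library size only and 54.2% with upper-quartile factors, against 49.4%. Removing the GC trend gave 3392 higher and 3453 lower, with 5563 genes called in both fits and none in opposite directions. The 2 fits differed in single genes: 1465 were called only without the removal and 1282 only with it. Counts of genes changed at least 2-fold fell to 449 higher and 339 lower with a mean of at least 10 CPM, where fewer genes were tested, to 380 and 325 with limma on log2(FPKM + 1), and to 366 and 322 on that scale without a filter, where the pseudocount shrinks low genes. Named genes kept their direction in all 1128 alternative values; 11 of these were no longer past the threshold, for DES, HIST1H1C and PKP3.

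The list tests depended most on the method. With an estimated correlation 0 lists were higher and 0 lower, and with fry, which does not compare a list with other genes, 21 were higher and 8 lower. Fry in limma turned the senescence list to higher, with an unadjusted value of 0.00720 and an adjusted p of 0.0122 (0.0122 to 0.989 over its alternatives); its median and mean differ in sign. Apart from the estimated correlation, 12 of the 13 lists stayed past the threshold in each alternative, with adjusted p up to 0.0400; the ribosomal list ranged from 6.00e-05 to 0.252. The difference in the share of the 10 most abundant genes was 1.85 percentage points without mitochondrial genes, and that in genes detected was 115 at 10 or more counts; the cause was not tested. Equal replicate numbers did not mark pairs: deviations of same-numbered libraries correlated at -0.077, 0.0009 and 0.0685, and the replicate block gave 3437 higher and 3552 lower.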

Other observations

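Of the tests given here, those on the GC trend, gene length, strongly changed genes, overlapping genes, fibroblast genes, transcription factor families and random gene sets, and the count over other splits, were chosen after the result was seen. That on ribosomal and respiratory genes of chromosome 11 was fixed before its result was seen. That on olfactory receptor genes was fixed before for all 381 (-12.9% of the needed rise) and narrowed after the result to those with a low mean, as OR2W3 alone went from 29.7 to 19.7 CPM. Chromosome, GC content, gene length, biotype and transcription factor family were all examined for patterns, and chromosome 11 was picked out among 23 chromosomes.

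Zinc finger genes of the C2H2 class are the largest family of transcription factors in the deposited annotation. They were 117 higher and 46 lower of 452 tested in OE CD51 ICD, against 3121 and 3411 of all 12137 protein-coding genes. Called rises were thus about as frequent as among all protein-coding genes, and called falls rarer. The median log2 fold change of the family was 0.28, or 0.19 with the GC trend removed. None of 10000 random draws of as many protein-coding genes had a median that high (highest 0.08). Such draws treat genes as independent, and the family was picked after its values were seen, so this share is not a p-value. The 184 members on chromosome 19 had a median of 0.23 and the 268 elsewhere 0.17 with the GC trend removed. Of 14 ARID family genes, which encode subunits of chromatin remodelling complexes among others, 9 were higher and 1 lower, with a median of 0.58 on that scale. The 46 bHLH genes were 14 higher and 22 lower, with a median of -0.21, or -0.04 with the GC trend removed.

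Genes on chromosome 11 were higher as a block in each OE CD51 ICD library. A few strongly changed genes do not account for this, since 69.9% of its genes were above 0 with the GC trend removed, against 49.3% elsewhere, and neither does the GC trend, after whose removal the median was 0.26. All 10 consecutive blocks of chromosome 11 genes had a median above 0 (0.16 to 0.37). Of 10000 random gene sets as large as chromosome 11, 0 reached a median of 0.26 (highest 0.08). Such sets treat genes as independent, and chromosome 11 was picked for its high median, so this share is not a p-value. The 11 ribosomal protein and oxidative phosphorylation genes there lay 0.27 above the 107 on other chromosomes, but 82.6% of random picks of 11 chromosome 11 genes lay at least 0.1 above other chromosomes, so this value follows from the pattern and does not separate causes. More copies of chromosome 11 in part or all of the OE CD51 ICD cells stay open as a cause, as no DNA was measured. So does a response of chromosome 11 genes to CD51-ICD. The median log2 fold change of 0.26 (1.20-fold) was below the 0.58 for 3 copies in place of 2 in all cells. It was also below the 0.42 for 4 copies in place of 3.

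The 13 lists past the threshold were set against library trends and another cell type. All 13 kept their call and direction with the GC trend removed, and 12 with the gene-length trend removed, the ribosomal list being the exception, so gene length may account for that list's call. Fibroblasts would bring COL1A2, COL3A1, DCN and LUM with COL1A1, but these 4 genes together reached 0.678 CPM in OE CD51 ICD, which is 0.0478% of the COL1A1 rise of 1419 CPM. Effects of CD51-ICD, of cell density or of time in culture stay open, since the labels separate none of them. The same holds for other differences between the cell populations, such as in copies of chromosome 11. It also holds for the RNA extraction method, which the labels do not assign to libraries.

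Non-coding genes (antisense, long intergenic, intronic and related classes) were 254 higher and 86 lower of 1090, with a median of 0.23, against -0.01 for protein-coding genes. Of 12137 protein-coding genes, 3121 were higher and 3411 lower, so called rises were no more frequent among non-coding genes and called falls were rarer. These call rates were not matched for level, and the non-coding genes had a median of only 1.61 CPM. Protein-coding genes matched to them on mean CPM had a median log2 fold change of 0.02 with the GC trend removed. The GC trend does not account for the higher median of the non-coding genes, which was 0.27 after its removal. Nor do reads of overlapping coding genes alone, as the 485 non-coding genes that overlap no tested coding gene had a median of 0.24. For the 605 that do overlap one, with a median of 0.30, such reads may be part of the cause: the change followed that of the overlapping coding gene (Spearman rho 0.38 across genes, which are not independent replicates), and the 256 whose coding gene was at or below 0 had a median of 0.12, all with the GC trend removed. Genomic DNA would raise silent genes too, but the 379 olfactory receptor genes with a mean under 1 CPM over all libraries went from a summed 1.08 ± 0.388 to 1.61 ± 0.542 CPM, 0.699% of the rise it would need. Retention of nuclear or unspliced RNA, or slower decay, may be a cause and was not tested.

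The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split was 1 of 10 to give 7028 changed genes, and 1 of 10 to give 1754 changed at least 2-fold. The highest of the other splits gave 0 for both with edgeR, where up to 294 genes had an unadjusted p under 0.05. DESeq2 called at most 1 gene there and limma-voom 0. Each of the other splits puts NC and OE CD51 ICD libraries together in both groups. The difference between NC and OE CD51 ICD then counts as spread within groups, which leaves few genes to call. These gene counts therefore do not show how many genes chance alone would call. For lists past the threshold by camera the real split gave 13 and the highest other split 10.

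The GC trend varied between libraries of a group too, but its sign was the same within each group and differed between the groups. The median of the 10% of genes lowest in GC content lay above that of the 10% highest by 0.25, 0.56 and 0.03 on the log2 scale in OE CD51 ICD replicates 1, 2 and 3, and by -0.15, -0.27 and -0.41 in NC replicates 1, 2 and 3.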
